A study of Homo sapiens with 26 samples.

How the data were processed

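Promoter occupancy of the histone variants macroH2A1 and macroH2A2 was measured by chromatin immunoprecipitation on promoter microarrays in NT2/D1, an established human embryonal carcinoma cell line. Per the labels, 13 immunoprecipitations were each hybridised to 2 array designs (A and B), which gave 26 arrays. IgG control immunoprecipitations numbered 3. MacroH2A1 was precipitated 2 times with a homemade antibody and 2 times with an antibody from Upstate, and macroH2A2 was precipitated 3 times. The remaining 3 immunoprecipitations used the macroH2A1 antibody on cells that stably express short hairpin RNA against both variants, called the knockdown below. The series text calls the replicates biological. One knockdown title repeats the replicate number of another, and that immunoprecipitation was counted as the third. On each array, per the labels, the red dye carried amplified immunoprecipitated DNA and the green dye carried input DNA of wild-type cells, for the knockdown as well. The input of the knockdown cells is therefore not part of its ratios.

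Per the file headers, the scanner software was Agilent Feature Extraction, in versions 9.5.1.1 and 9.5.3.1. The processed signal of each channel is, per the file headers, a fluorescence intensity after background subtraction, detrending and linear dye normalisation by that software. Its LogRatio column is, per the file headers, a log10 of red over green. The deposited table of values holds 1 score per probe and array, a normalised log ratio made by the authors whose base and scaling are not given in the sources used here. Over probes, the Pearson correlation of that score with the scanner log10 ratio was 0.525 to 0.953 by array and its slope 0.156 to 2.26, so the score served only as an alternative. The submitters' processing notes name limma, without a version. The genome build of the probe positions is not given in the sources used here.

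From the deposited processed intensities, a log2 ratio of red over green was computed for every probe, with control spots and spots that the scanner software marked as outliers left out. Each array was centred on its median. Ratios were averaged over all probes of a gene name with at least 5 probes, and the gene names of both designs were stacked by immunoprecipitation. Names on more than 1 chromosome or on both designs were left out. This gave 17458 promoters, 8450 on design A and 9008 on design B, from 237210 and 237201 probes. Current gene symbols came from a RefSeq table joined by transcript, which was used for names only. The share of spots left out as outliers was 0.0059% to 0.116% per array.

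Signal over background takes the place of depth on arrays. In the red channel, 61.3% to 92.7% of probes lay well above background on the IgG arrays, and 85.5% to 99.0% on all others. The scanner multiplier behind that mark was 13 for IgG replicates 2 and 3 and 2.6 for the rest. The number of arrays, with groups of 2 to 4 immunoprecipitations, limits the precision.

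All 5 groups entered a single limma fit (limma 3.58.1, lmFit and eBayes), and a promoter passed at a Benjamini-Hochberg adjusted p under 0.05 over all promoters of both designs. The residual degrees of freedom were 8, with 8.70 added by the prior. Of the 6 comparisons, 4 were main: macroH2A1 (mean of both antibodies) minus IgG, macroH2A2 minus IgG, macroH2A1 with the homemade antibody in wild-type minus knockdown cells, and macroH2A1 minus macroH2A2. The other two were the homemade minus the Upstate antibody and the knockdown minus IgG. Gene lists, comparisons, tests, naming rule and most alternatives were fixed before the data were examined.

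The 31 gene lists hold the 4 HOX clusters, developmental transcription factors, morphogen and growth factor ligands, pluripotency, neuronal, retinoic acid response and imprinted genes. Housekeeping lists hold ribosomal, mitochondrial ribosomal, proteasome, splicing, oxidative phosphorylation, RNA polymerase and general transcription factor, histone, ZNF and cell cycle genes. Further lists hold protocadherin, olfactory receptor, taste receptor, keratin, beta-defensin, cancer-testis, interferon and cytokine, blood cell, liver and muscle genes, cell cycle inhibitors with tumour suppressors, and Polycomb with chromatin regulators. Each list was set against all other promoters with camera at a preset inter-gene correlation of 0.01 for each main comparison, which made 124 tests, adjusted over the 31 lists of a comparison. Camera with the correlation estimated from the data, and fry, which tests whether members move on balance one way, were alternatives. Promoters of a list were also adjusted over the list alone.

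Genes were named by rule. For each main comparison the rule took the 10 largest increases and 6 largest decreases among promoters that passed with no overlap between the groups' values. Where none passed, it took the 5 smallest unadjusted p. It added up to 3 members with the largest absolute difference of each called list and of each HOX cluster. For the antibody comparison and for the knockdown against IgG it took the 3 largest increases and 3 largest decreases, or, where none passed, the 5 smallest unadjusted p. H2AFY and H2AFY2, which encode the variants, were added as background. Promoters with several symbols or none were not named. Some promoters that the rule names are left out of the text because their names are withheld.

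Positions relative to the transcription start came from the array annotation. Probe ratios were averaged in bins of 500 bp, and the bin at the start minus the bins over 2 kb upstream was compared between groups with an exact two-sided permutation test, with Benjamini-Hochberg adjustment over 3 groups.

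Alternatives were normexp background correction with an offset of 50, loess within each array with a span of 0.3, no centring, scaling of arrays to the same spread, probes well above background only, the median of the probes, the authors' scores, at least 10 probes, a block by replicate number, a block by scan batch, the first scan batch alone, only the groups compared, eBayes with a trend and robust, each design on its own, single antibodies, and leaving out each immunoprecipitation. Arrays were grouped by the month and year of their scan, which gave 4 batches. The first holds 7 immunoprecipitations (1 IgG, both homemade, 3 macroH2A2 and 1 knockdown), and the others hold 2 Upstate, 2 IgG and 2 knockdown immunoprecipitations, each alone. Chosen after seeing the data were a correction of each array for GC content by splines with 4 degrees of freedom, that correction with scaling, and scan batch as a random block.

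The fit was tested on simulated data in which 200 of 17458 promoters were shifted. A log2 shift of 1 was recovered at 92.1% to 98.1% of them on average by comparison, and a shift of 0.5 at 7.7% to 43.3%. The median number of false calls was 0 to 0.5. False calls reached 1069 in a simulation of wild type against knockdown and 678 in a simulation of macroH2A2 against IgG. A gene list shifted by 0.5 was called in 10 of 10 simulations, but 6.8 to 10.1 unshifted lists were called beside it. Computations used R 4.3.3, data.table (1.17.8), arrow 21.0.0, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. No array was left out. Probes outside named promoters are described in the closing section only.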

Results

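MacroH2A1 and macroH2A2 are histone variants with a large non-histone macrodomain, and the series measured where they sit at gene promoters in undifferentiated NT2/D1 cells. The data are 26 two-colour promoter arrays of 13 immunoprecipitations: 3 with IgG, 2 with a homemade and 2 with an Upstate macroH2A1 antibody, 3 with a macroH2A2 antibody, and 3 with the macroH2A1 antibody in cells carrying short hairpin RNA against both variants. Values below are mean log2 ratios of immunoprecipitated over input DNA for 17458 promoters, with array medians set to 0. Immunoprecipitated signal was well above background at 61.3 to 92.7% of probes on IgG arrays and 85.5 to 99.0% on the others, with a stricter scanner mark on IgG replicates 2 and 3. Medians before centring ran from −0.36 to 0.05. The SD of probe ratios on an array was 0.58 to 0.72 for macroH2A2, 0.67 to 1.06 for the homemade antibody, 1.01 to 1.11 for the Upstate antibody, 0.92 to 1.38 for IgG and 1.07 to 1.57 for the knockdown. On every array promoter values rose with the GC content of the probes (Pearson r across promoters, which are not independent replicates, 0.430 to 0.821). Across promoters, r between immunoprecipitations was 0.892 to 0.932 within IgG, 0.832 to 0.986 within macroH2A1, 0.83 to 0.93 within macroH2A2 and 0.95 to 0.99 within the knockdown. The knockdown correlated with IgG at 0.895 to 0.960, macroH2A1 with IgG at 0.785 to 0.885, and macroH2A1 with macroH2A2 at 0.723 to 0.948.

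The first comparison, macroH2A1 against IgG, asks which promoters carry macroH2A1. Promoters of many developmental and tissue-restricted genes were higher with macroH2A1 than with IgG. The largest difference was at GIMAP5, a GTPase gene of lymphocytes (chromosome 7, 150060097 to 150067621), which averaged 1.66 ± 0.29 (SD, n = 4) with macroH2A1 and −0.31 ± 0.20 (SD, n = 3) with IgG. EOMES, a T-box regulator of early lineages (chromosome 3, 27736303 to 27744277), averaged 1.17 ± 0.24 (n = 4) against −0.28 ± 0.16 (n = 3). Of the homeobox genes that pattern the body axis, 32 of 39 HOX promoters were higher, by 1.15 ± 0.14 (SE) at HOXA4 (chromosome 7, 27134566 to 27142234). Decreases were fewer and smaller, with STX19, a syntaxin gene (chromosome 3, 95227904 to 95230694), lower by a log2 difference of −0.79 ± 0.14 (SE).

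The next largest increases were at AK3L1 (AK4, a mitochondrial adenylate kinase, 1.59 ± 0.17 SE) and FLJ20184 (ARHGEF38, 1.58 ± 0.16). CLEC4C, a C-type lectin gene of plasmacytoid dendritic cells, rose by 1.46 ± 0.26, from −2.05 ± 0.77 (SD, n = 3) in IgG to −0.59 ± 0.13 (SD, n = 4). It lies in the first 35 Mb of chromosome 12, where the input signal was brighter than at promoters of like GC content, by 0.73 ± 0.12 (SD, n = 3) on the IgG arrays. RXRG, a retinoid receptor, rose by 1.42 ± 0.15, CER1, a secreted Nodal and BMP antagonist, by 1.39 ± 0.17, CX62 (GJA10, a connexin) by 1.38 ± 0.13, AFF3 by 1.31 ± 0.13 and GLRA1, a glycine receptor subunit, by 1.30 ± 0.13. Adjusted p for these 10 promoters, GIMAP5 and EOMES included, ran from 3.23e-06 to 0.00188 in limma, and no macroH2A1 value fell among the IgG values. The other decreases were LZIC (−0.81 ± 0.17), RARB, a retinoic acid receptor (−0.73 ± 0.20), ZNF234 (−0.64 ± 0.13), MDN1 (−0.63 ± 0.13) and CLCN3, a chloride transporter (−0.62 ± 0.15). RARB was lost without IgG replicate 2 (adjusted p = 0.0698) or 3 (0.149, log2 −0.41), homemade replicate 1 (0.059), or Upstate replicate 3 (0.0595) or 4 (0.0515), and CLCN3 without IgG replicate 3 (0.104) or homemade replicate 1 (0.0623). The promoters of the genes that encode the variants were not called: H2AFY (MACROH2A1) averaged 0.30 ± 0.07 (SD, n = 4) against 0.20 ± 0.11 in IgG, and H2AFY2 (MACROH2A2) −0.23 ± 0.04 against −0.47 ± 0.20.

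Within the HOX clusters, 11 of 11 HOXA, 9 of 10 HOXB, 8 of 9 HOXC and 4 of 9 HOXD promoters rose, and adjusted over the list alone 11, 10, 9 and 6 did. HOXA10 rose by 0.83 ± 0.12 (SE), HOXB3 by 0.88 ± 0.12, HOXB6 by 0.80 ± 0.10, HOXC11 by 0.81 ± 0.12, HOXC4 by 0.76 ± 0.10 and HOXD13 by 0.58 ± 0.12. HOXD3 rose by 0.51 ± 0.13, but its adjusted p was 0.075 without IgG replicate 2 and 0.0843 without IgG replicate 3. Against other promoters the clusters stood higher by 0.56 (HOXA, camera adjusted p = 2.29e-09), 0.42 (HOXB, 1.45e-07), 0.44 (HOXC, 1.78e-07) and 0.18 (HOXD, 0.0136). The estimated correlation gave an adjusted p of 0.578 for HOXA, HOXB and HOXC and 0.743 for HOXD. In 6 of 100 simulations of unchanged groups the HOXD list moved as far.

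**Figure D1:**
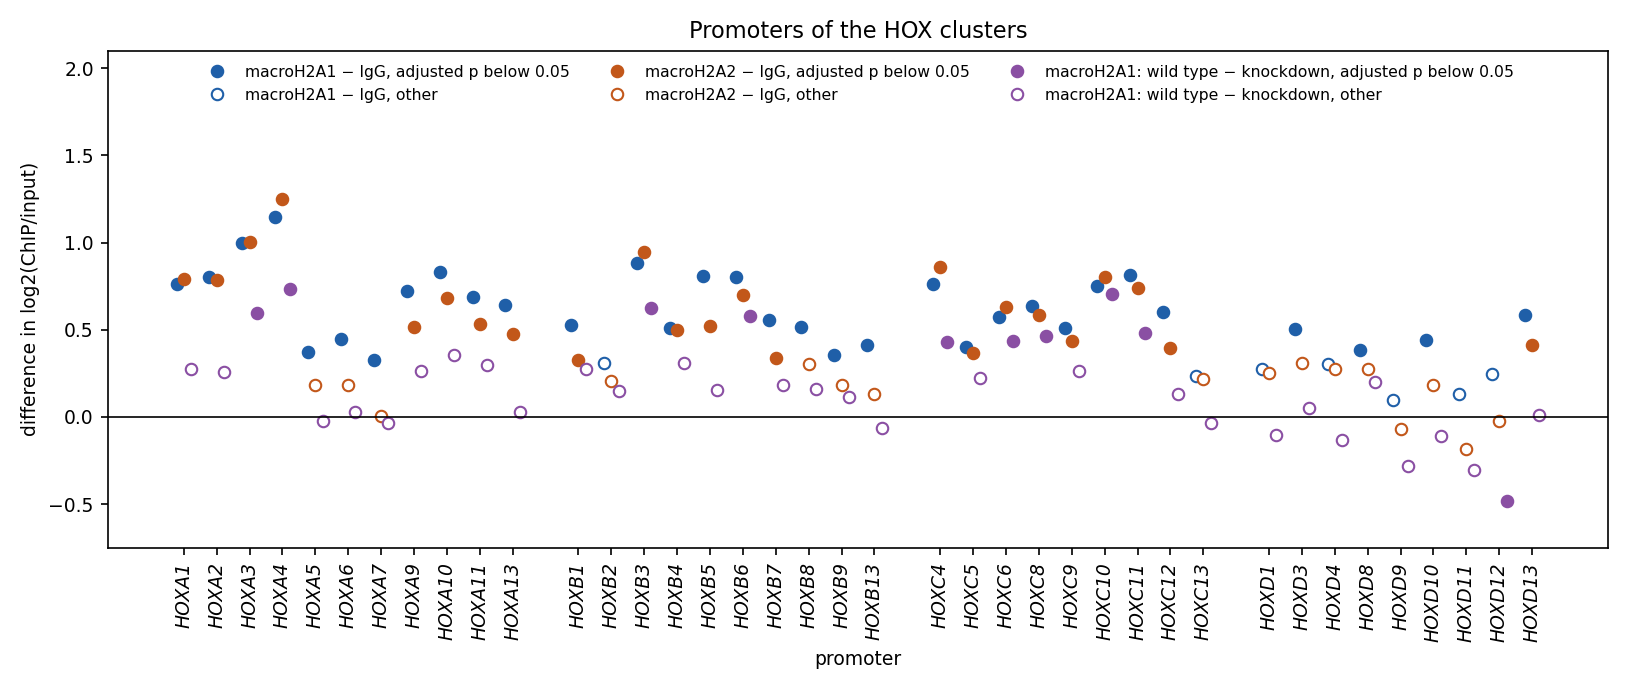
Log2 difference (y axis) of each of the 39 HOX promoters (x axis, by cluster) in macroH2A1 against IgG, macroH2A2 against IgG and wild type against knockdown, with filled points where the limma adjusted p was below 0.05. MacroH2A1 against IgG fills 32 points, macroH2A2 against IgG 23, and wild type against knockdown 10, of which 1 (HOXD12) is negative.

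Developmental transcription factors rose at 80 of 186 promoters and fell at none, and at 111 adjusted over the list alone (camera adjusted p = 1.35e-12, and 0.714 with an estimated correlation). HESX1, a forebrain and pituitary homeobox gene, rose by 1.24 ± 0.15 (SE), and NEUROD1, a neuronal and pancreatic helix-loop-helix gene, by 1.23 ± 0.12. Of 71 morphogen and growth factor ligands 22 rose (30 adjusted over the list alone), among them WNT8B (0.91 ± 0.13) and SFRP4, a WNT antagonist (0.85 ± 0.13). The camera adjusted p was 4.37e-05, and 0.743 with an estimated correlation. Neuronal genes rose at 29 of 74 promoters (38 adjusted over the list alone; camera 1.46e-05, estimated correlation adjusted p = 0.714), with the hormone gene SST at 1.28 ± 0.11 and the glutamate receptor gene GRIK1 at 0.79 ± 0.14.

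Some lists of genes expressed in few tissues rose as well. Keratin genes rose at 41 of 85 promoters (51 adjusted over the list alone, camera adjusted p = 4.11e-08), with KRT3 at 0.85 ± 0.16 (SE). Beta-defensins rose at 6 of 9 (9 adjusted over the list alone, 4.37e-05), with DEFB32 (DEFB132) at 0.93 ± 0.16 and DEFB123 at 0.78 ± 0.16. Blood cell genes rose at 14 of 38 (24 adjusted over the list alone, 4.37e-05), with the fetal globin gene HBG2 at 0.91 ± 0.16. Interferon and cytokine genes rose at 28 of 92 (37 adjusted over the list alone, 4.45e-05), with IL9 at 0.76 ± 0.11. Olfactory receptors rose at 77 of 296 (105 adjusted over the list alone, 2.56e-05), with OR4X1 at 1.01 ± 0.16, but that list stood at −0.01 against other promoters after loess and at −0.03 in the authors' scores, 14 of 100 simulations of unchanged groups moved it as far, and fry did not call it (adjusted p = 0.0799). With an estimated correlation the adjusted p was 0.714 for keratins and blood cell genes, 0.68 for beta-defensins, and 0.743 for cytokines and olfactory receptors.

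Housekeeping lists other than the histone list stood lower than other promoters while their medians lay between 0.00 and 0.06, and few members passed. Their medians are thus not below 0 although camera ranks them below other promoters, and fry gave the direction as up in all of these lists but the RNA polymerase list (fry adjusted p 0.448 to 0.963). The list differences were −0.15 for RNA polymerase and general transcription factor genes (1 of 58 rose and 2 fell, camera adjusted p = 5.73e-05) and −0.14 for splicing factors (1 of 72 rose, 5.73e-05). They were −0.10 for ribosomal proteins (2 of 75 rose, 0.00399), −0.09 for mitochondrial ribosomal proteins (1 of 74 rose, 0.00875) and −0.09 for proteasome subunits (4 of 43 rose and 2 fell, 0.0253). Oxidative phosphorylation genes stood at −0.08 (2 of 75 rose, 0.0171), ZNF genes at −0.08 (24 of 403 rose and 3 fell, 0.0028) and cell cycle genes at −0.11 (2 of 40 rose, 0.0183). With an estimated correlation the adjusted p was 0.714 for the RNA polymerase list and 0.743 for the other lists of this paragraph. Adjusted over the list alone, the counts that rose and fell were 1 and 1 (RNA polymerase), 3 and 1 (proteasome), 14 and 1 (ZNF) and 2 and 0 (cell cycle), and 0 in the rest. TAF11, a TFIID subunit, fell by 0.49 ± 0.09 (SE), and the immunoproteasome gene PSMB8 rose by 0.70 ± 0.13.

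In the lists not called, 7 of 39 pluripotency, 5 of 22 retinoic acid response, 8 of 33 imprinted, 8 of 50 histone, 3 of 38 protocadherin and 3 of 20 taste receptor promoters rose. The same held for 9 of 45 cancer-testis, 6 of 30 liver, 5 of 34 muscle and 5 of 23 cell cycle inhibitor promoters, and for 0 of 34 Polycomb and chromatin regulators. Their camera adjusted p ran from 0.085 to 0.509. A retinoic acid response gene (RARB) and 1 histone gene fell.

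Across all promoters 2653 rose and 58 fell in limma, with 5056 at an unadjusted p under 0.05. The called counts hung on the background method: 0 promoters passed with normexp background correction (892 at an unadjusted p under 0.05). With scan batch as a block 0 passed (1580), but that contrast held the homemade antibody alone. Its differences equal those within the first batch, with 1 IgG and 2 homemade immunoprecipitations. It therefore cannot tell scan batch from the loss of samples. Within that batch GIMAP5 stood at 1.85, EOMES at 1.32 and HOXA4 at 0.74. Increases numbered 886 without IgG replicate 3, 888 without IgG replicate 2, 1640 without homemade replicate 1, 1362 and 1432 without Upstate replicates 3 and 4, and 5363 without IgG replicate 1, and increases were 97.9% of calls, 67.3% after loess (2251 rose and 1093 fell) and 62.4% after GC correction (2546 rose and 1531 fell).

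Without centring, the median difference over all promoters moved from 0.12 to 0.24 in macroH2A1 against IgG, from 0.08 to 0.23 in macroH2A2 against IgG and from −0.07 to 0.08 in wild type against knockdown.

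**Figure D2:**
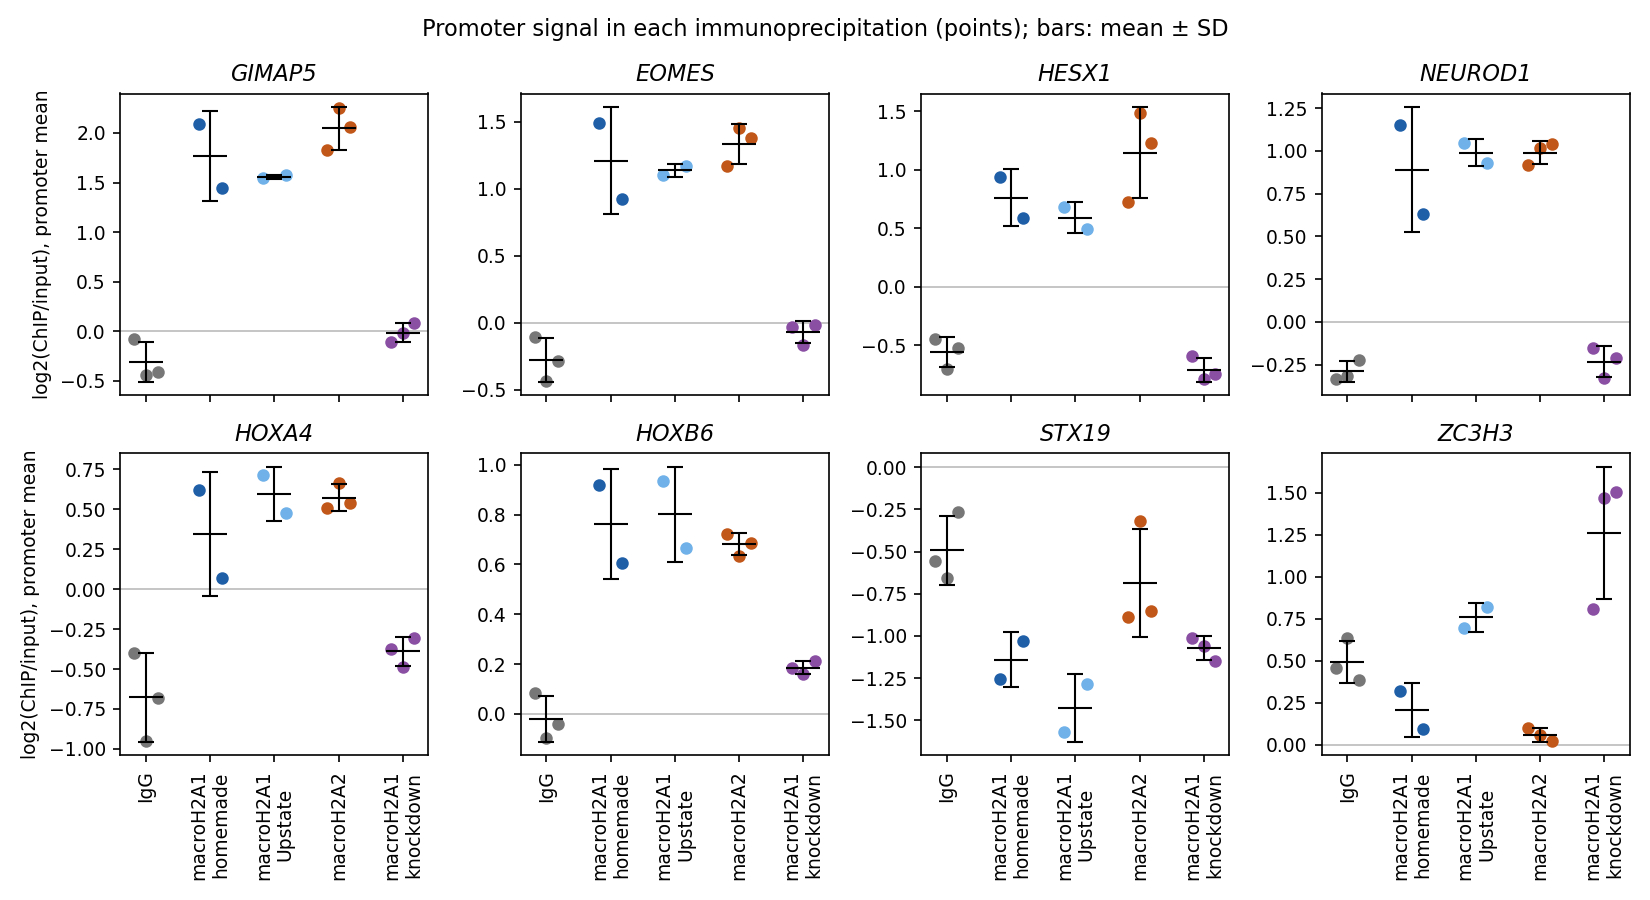
Log2 ratio of immunoprecipitated over input DNA (y axis) at 8 promoters in each immunoprecipitation (points) of the 5 groups, with group means and SD. GIMAP5 averaged −0.31 in IgG, 1.77 with the homemade macroH2A1 antibody, 2.05 with macroH2A2 and −0.01 in the knockdown.

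MacroH2A2 against IgG asks the same of the other variant. The macroH2A2 promoters with the largest increases held many of the same genes, led again by GIMAP5 at 2.05 ± 0.21 (SD, n = 3) against −0.31 ± 0.20 (SD, n = 3), a difference of 2.35 ± 0.16 (SE, adjusted p = 5.82e-07). HESX1 averaged 1.15 ± 0.39 (n = 3) against −0.56 ± 0.13 (chromosome 3, 57206646 to 57213133). Olfactory receptor promoters rose at 206 of 296, a wide move of a family expressed mainly in the nose, which stood at 0.42 against other promoters but at −0.03 in the authors' scores, with a camera adjusted p of 0.925 under an estimated correlation. Their median GC content was 32.7%, against 42.2% for all promoters, and the macroH2A2 differences fell with GC content (r = −0.558 across promoters). The move may thus follow GC content rather than the family. Decreases reached −0.91 ± 0.17 (SE) at C6orf153 (RRP36, a ribosome biogenesis gene; chromosome 6, 43097008 to 43097807).

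Other large increases were at FLJ20184 (1.95 ± 0.17 SE), CER1 (1.86 ± 0.18), AK3L1 (1.84 ± 0.19), RGSL2 (1.77 ± 0.14) and ANKRD1, a cardiac ankyrin repeat gene (1.69 ± 0.17). The lectin receptor genes CLEC4C (2.19 ± 0.27), KLRC3 (1.89 ± 0.23) and CLEC7A (1.69 ± 0.21) lie in the first 35 Mb of chromosome 12, where 76.1% of 264 promoters rose against 19.3% elsewhere. Decreases included NDUFS6, a respiratory complex I subunit (−0.72 ± 0.14), and GATS (−0.71 ± 0.12). PTPRU (−0.74 ± 0.18) was lost without IgG replicate 2 (adjusted p = 0.0544), and RAB42 (−0.73 ± 0.17) was lost after GC correction. The H2AFY2 promoter rose by 0.48 ± 0.12 (adjusted p = 0.00927), a call lost without IgG replicate 3 (0.0565), without macroH2A2 replicate 2 (0.0628) and after GC correction.

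HOXA promoters rose at 8 of 11 (0.46 against other promoters, camera adjusted p = 0.00038), HOXB at 6 of 10 (0.29, 0.00611) and HOXC at 8 of 9 (0.44, 0.000155), and adjusted over the list alone 8, 7 and 8 did, but with an estimated correlation the adjusted p was 0.925 for each. HOXA4 rose by 1.25 ± 0.15 (SE), HOXB3 by 0.95 ± 0.13, HOXB6 by 0.70 ± 0.11 and HOXC4 by 0.86 ± 0.11. In HOXD 1 of 9 rose (camera adjusted p = 0.558), namely HOXD13 at 0.41 ± 0.12, which was lost without IgG replicate 2 or 3 and without macroH2A2 replicate 2 or 3. Developmental transcription factors rose at 61 of 186 and fell at 3, with 62 and 3 adjusted over the list alone (0.10 against other promoters but −0.01 with normexp, camera adjusted p = 0.00926, and 0.925 with an estimated correlation), and 15 of 100 simulations of unchanged groups moved that list as far. EOMES rose by 1.61 ± 0.14 and NEUROD1 by 1.28 ± 0.12.

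Olfactory receptors, with OR4X1 at 1.46 ± 0.17 (SE), had a camera adjusted p of 1.02e-20, and 232 rose and 1 fell adjusted over the list alone. Keratins rose at 51 of 85 and fell at 1 (58 and 1 adjusted over the list alone, 5.03e-10), with KRT6B at 1.40 ± 0.18. Beta-defensins rose at 7 of 9 (8 adjusted over the list alone, 0.000133), with DEFB129 at 1.17 ± 0.19. Blood cell genes rose at 16 of 38 (19 and 1 lower adjusted over the list alone, 0.0182), with HBG2 at 1.49 ± 0.17, and cytokines at 36 of 92 (36 and 1 lower adjusted over the list alone, 0.0116), with IL20 at 0.90 ± 0.12. RNA polymerase and general transcription factor genes stood at −0.15 (5 of 58 rose and 9 fell over all promoters and over the list alone, 0.0104). The adjusted p with an estimated correlation was 0.925 for every called list of this comparison. Among the lists not called, 24 of 74 neuronal, 18 of 71 ligand, 8 of 39 pluripotency and 9 of 20 taste receptor promoters rose.

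In all, 3524 promoters rose and 834 fell (limma, 6768 at an unadjusted p under 0.05). Promoters that rose had a median GC content of 38.0% and those that fell 51.2%, against 42.2% for all. No promoter passed with normexp (2952 at an unadjusted p under 0.05) or within the first batch (2366), where GIMAP5 stood at 2.13 with its 1 IgG immunoprecipitation. Increases were 80.9% of calls but 58.2% with arrays scaled to the same spread, 98.2% without centring and 51.0% after GC correction, and they numbered 1963 without macroH2A2 replicate 2, 2162 without macroH2A2 replicate 3, 2015 and 2029 without IgG replicates 2 and 3, and 5729 without IgG replicate 1.

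Shared targets were counted because the series profiles both variants. Promoters that rose with both variants numbered 2059, where independent lists of these sizes would share 536, and 29 fell with both, where 2.77 would. GIMAP5, EOMES, HESX1, HOXA4 and HOXC4 were among those that rose with both. The differences correlated across promoters at r = 0.753, but both use the same IgG arrays. In 100 simulations of unchanged groups the shared controls alone gave a mean r of 0.493 and a highest r of 0.906, so r does not set the observed value apart. The mean simulated covariance was 0.00725 (highest 0.0272) against 0.0574 observed. Shared calls in the simulations numbered at most 0, but unchanged groups hold no true calls to share, so that count decides nothing. With separate controls, promoters higher in wild type than in knockdown and higher with macroH2A2 than IgG numbered 633, where independent lists would share 137, and 487 were lower in both, where 79.6 would be. Both differences fell with GC content (r = −0.467 and −0.558 across promoters), so independent lists are not a fair value for no sharing. Only 31 promoters were higher in wild type without knockdown replicate 2 and 63 without replicate 3. Both homemade and all macroH2A2 immunoprecipitations lie in the first scan batch, with IgG and knockdown replicates 2 and 3 in others. Scan batch could thus move both differences alike. With scan batch as a block, wild type against knockdown gave 5 and 0, but its differences then rest on knockdown replicate 1 alone. Across promoters these differences correlated at r = 0.796 (covariance 0.0810), above the simulated highest of 0.692 (0.0137). The simulations shuffled deviations over all samples, so they cannot speak to scan batch. The shared count was 0 with normexp, 1940 after GC correction, 740 without IgG replicate 2 and 4215 without IgG replicate 1.

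Wild type against knockdown, with the homemade macroH2A1 antibody in both, asks whether the signal depends on the variants. The signal at the leading promoters was low in the knockdown, but they were picked for large differences on these same arrays. Of the 2653 promoters higher with macroH2A1 than with IgG, 565 were also called higher in wild type than in knockdown. GIMAP5 averaged 1.77 ± 0.45 (SD, n = 2) in wild-type and −0.01 ± 0.09 (SD, n = 3) in knockdown cells, and EOMES 1.21 ± 0.40 (n = 2) against −0.07 ± 0.08 (n = 3). HESX1 was higher in wild type by 1.47 ± 0.18 (SE, adjusted p = 0.00091), SST by 1.21 ± 0.13 (0.000382) and NEUROD1 by 1.12 ± 0.14 (0.00091). Among promoters lower in wild type, ZC3H3, a zinc finger gene, stood at 0.21 ± 0.16 (SD, n = 2) against 1.26 ± 0.39 (SD, n = 3; chromosome 8, 144692275 to 144697886).

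FLJ20184 (1.5 ± 0.19 SE), CX62 (1.45 ± 0.16), AK3L1 (1.41 ± 0.21) and CRYGD, a lens crystallin gene (1.36 ± 0.24), were higher in wild type. So were KLRC3 (1.47 ± 0.26), CD163, a macrophage scavenger receptor gene (1.38 ± 0.30), and APOBEC1, a cytidine deaminase gene (1.29 ± 0.21), all within the bright input region of chromosome 12. Lower in wild type were EVC2, a cilium gene (−1.14 ± 0.27), MON1A (−1.05 ± 0.17), POLE3, a DNA polymerase subunit gene (−1.03 ± 0.20), and ARL9 (−1.03 ± 0.17). The H2AFY promoter averaged 0.29 ± 0.12 (SD, n = 2) against 0.21 ± 0.07 (SD, n = 3) and was not called, and immunoprecipitation does not measure how far the knockdown lowered either protein.

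HOXA was higher in wild type at 2 of 11 promoters (camera adjusted p = 0.00344), HOXB at 2 of 10 (0.00156) and HOXC at 5 of 9 (0.000112), with the same counts adjusted over the list alone, but with an estimated correlation the adjusted p was 0.896 for each. HOXA4 rose by 0.74 ± 0.17 (SE), HOXB3 by 0.62 ± 0.14, HOXB6 by 0.58 ± 0.13 and HOXC10 by 0.71 ± 0.15, while HOXD12 fell by 0.48 ± 0.15. Without homemade replicate 1 the adjusted p of these HOXA4, HOXB3, HOXB6 and HOXC10 calls rose to 0.0543 to 0.096, they were lost without knockdown replicate 2 or 3 as well, and HOXD12 kept its call in 8 of 31 alternatives. The HOXA list stood at 0.31 against other promoters but at −0.23 with normexp, and without homemade replicate 1 the HOXA, HOXB and HOXC lists stood at 0.04, 0.19 and 0.24 with adjusted p of 0.851, 0.13 and 0.064. Developmental transcription factors were higher at 16 of 186 and lower at 2 (13 and 2 adjusted over the list alone, 0.00398, and 0.896 with an estimated correlation), with the list at 0.11 but at −0.03 without homemade replicate 1 and −0.11 with normexp, and 18 of 100 simulations of unchanged groups moved it as far. Neuronal genes were higher at 9 of 74 and lower at 4 (11 and 9 adjusted over the list alone, 0.0208, and 0.896 with an estimated correlation), a call that ended without homemade replicate 1.

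Among tissue-restricted families, olfactory receptors were higher at 44 of 296 and lower at 2 (53 and 2 adjusted over the list alone, camera adjusted p = 2.36e-21), standing at 0.36 but at −0.10 with arrays scaled to the same spread and −0.02 in the authors' scores. Their promoters are poor in GC (median 32.7%), and differences in this comparison fell with GC content (r = −0.467 across promoters). Keratins were higher at 15 of 85 and lower at 2 (18 and 2 adjusted over the list alone, 5.34e-08), with KRT6B at 1.07 ± 0.20 (SE), and beta-defensins at 3 of 9 (6 and 1 lower adjusted over the list alone, 0.000356), with DEFB123 at 0.86 ± 0.19. Histone genes were higher at 4 of 50 (1 adjusted over the list alone, 0.00134), with HIST1H2AA (H2AC1) at 0.96 ± 0.17, but the list stood at −0.06 without homemade replicate 2, −0.05 over well measured probes and −0.02 in the authors' scores, and 19 of 100 simulations of unchanged groups moved it as far. Blood cell genes (3 of 38 higher and 1 lower, 0.0164), liver genes (2 of 30 and 1, 0.0384) and cytokines (9 of 92 and 7, 0.0351; the list at −0.01 over well measured probes) lost their calls without homemade replicate 1. For all 7 lists of this paragraph the estimated correlation gave an adjusted p of 0.896.

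Ribosomal protein genes were lower in wild type at 17 of 75 promoters and higher at 1 (20 and 2 adjusted over the list alone, camera adjusted p = 0.00976), with RPS13 at −0.82 ± 0.21 (SE), RPL12 at −0.80 ± 0.19 and RPS3 at 0.80 ± 0.17. Mitochondrial ribosomal genes were lower at 11 of 74 (11 adjusted over the list alone, 0.0428), with MRPS34 at −0.80 ± 0.17. Cell cycle genes were lower at 6 of 40 (7 adjusted over the list alone, 0.0469), with CDC20, an activator of mitotic exit, at −0.77 ± 0.14 and MCM7, a replicative helicase subunit gene, at −0.70 ± 0.14. All 3 calls ended without homemade replicate 1. The adjusted p with an estimated correlation was 0.896 for every called list of this comparison, and fry called none. Over the 4 main comparisons camera called 49 of 124 list tests with the preset correlation, 0 with an estimated correlation, and fry called 26. In 100 simulations of unchanged groups camera with the preset correlation still called a mean of 7.63 of 31 lists in macroH2A1 against IgG, 7.9 in macroH2A2 against IgG, 8.43 in wild type against knockdown and 7.85 between the variants, where 20, 10, 15 and 4 were observed. As many were called in 1, 42, 16 and 75 of the 100 simulations.

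Altogether 678 promoters were higher and 1667 lower in wild type (limma, 5490 at an unadjusted p under 0.05). The median GC content was 37.0% for the former and 48.5% for the latter. With arrays scaled to the same spread, 137 of the 678 and 175 of the 1667 were kept, and 97 and 281 turned sign. Across promoters the scaled differences correlated with the main ones at r = 0.357. Without knockdown replicate 2, 31 promoters were higher and 5 lower, without knockdown replicate 3 the counts were 63 and 9, without homemade replicate 2 they were 197 and 84, and without knockdown replicate 1, 3252 were lower, and 11 of the 45 named promoters, among them GIMAP5, EOMES, HESX1, SST, NEUROD1, ZC3H3 and ARL9, passed in every such fit. Higher promoters made up 28.9% of calls, 54.0% with normexp, 52.4% after loess and 89.2% without centring, and within the first batch, with 1 knockdown immunoprecipitation, GIMAP5 stood at 1.88 and EOMES at 1.24 with no promoter passing (1039 at an unadjusted p under 0.05).

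**Figure D3:**
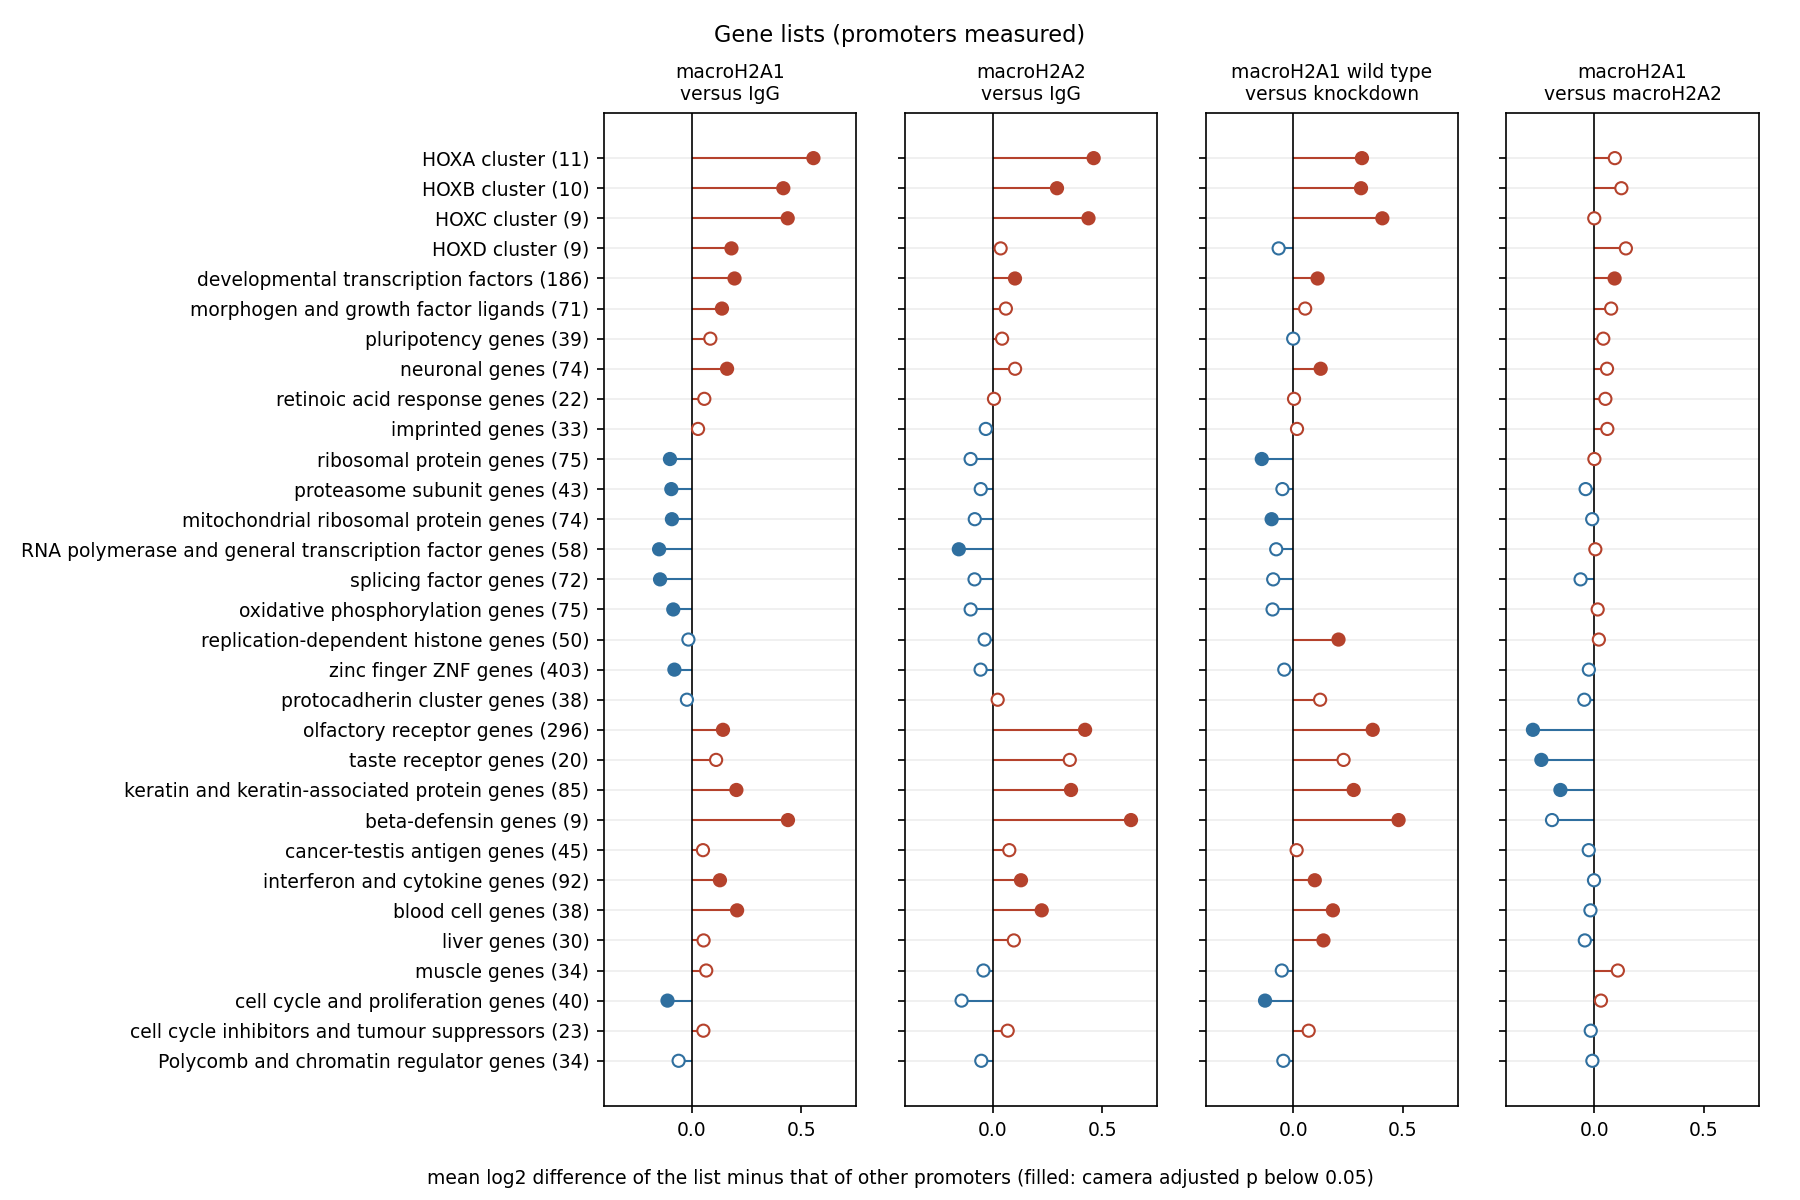
Mean log2 difference of each of the 31 gene lists minus that of all other promoters (x axis) in the 4 main comparisons, with filled points where the camera adjusted p with the preset correlation was below 0.05. HOXA stood at 0.56 in macroH2A1 against IgG, and olfactory receptors stood at 0.36 in wild type against knockdown, where scaling arrays to the same spread turned them to −0.10.

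MacroH2A1 against macroH2A2 asks whether the variants differ in place. No promoter passed (limma, smallest adjusted p = 0.102, 4488 at an unadjusted p under 0.05), so the genes below are those with the smallest unadjusted p. AGER, a receptor gene of the immunoglobulin family (chromosome 6, 32256696 to 32260482), averaged 0.88 ± 0.23 (SD, n = 4) with macroH2A1 and 0.18 ± 0.05 (SD, n = 3) with macroH2A2. At the AGER promoter macroH2A1 was not called against IgG (adjusted p = 0.987) and macroH2A2 fell against IgG by 0.70 (0.00088). POR, the cytochrome P450 reductase gene, differed by 0.65 ± 0.12 (SE), WDR6 by 0.67 ± 0.13, TXNRD2, a mitochondrial thioredoxin reductase gene, by 0.71 ± 0.14, and C15orf34 by −0.66 ± 0.12.

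As lists, olfactory receptors stood lower with macroH2A1 by a log2 difference of −0.28 (camera adjusted p = 3.92e-23; 0.01 in the authors' scores), keratins by −0.15 (0.00134) and taste receptors by −0.24 (0.0487; 0.17 with arrays scaled to the same spread). Developmental transcription factors stood higher by 0.09 (0.00283), which scaling turned to −0.22. In 21 of 100 simulations of unchanged groups that list moved as far, and within the first batch neither it (adjusted p = 0.155) nor the taste receptor list (0.108) was called. The taste receptor list kept its call in 11 of 27 alternatives. With an estimated correlation the adjusted p was 0.995 for these 4 lists, and adjusted over the list alone 7 of 20 taste receptor promoters were lower and 1 higher and the other three lists had 0. IRX4 and SIX3, homeobox genes, each differed by 0.50 (SE 0.13 and 0.12), OR6C6 by −0.68 ± 0.20, KRTAP8-1 by −0.59 ± 0.18 and TAS2R50, in the bright input region of chromosome 12, by −0.76 ± 0.23, none past the threshold. The HOX clusters differed from other promoters by 0.09 (HOXA), 0.12 (HOXB), 0.00 (HOXC) and 0.14 (HOXD) with camera adjusted p of 0.349, 0.18, 0.982 and 0.18, but with arrays scaled to the same spread the mean difference of the 39 HOX promoters turned from 0.12 to −0.24 and 14 were lower. Differences between the variants rose with GC content (r = 0.737 across promoters), and without homemade replicate 2, 2105 promoters were higher with macroH2A1 and 512 lower, AGER and POR among the former, and without knockdown replicate 1 the counts were 647 and 68. Scaling the arrays called 484 and 225, and within the first batch none passed (1032 at an unadjusted p under 0.05).

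Between the macroH2A1 antibodies no promoter passed (limma, smallest adjusted p = 0.536, 1611 at an unadjusted p under 0.05). The smallest unadjusted p belonged to ABCF1, a translation factor gene, at 0.74 ± 0.15 (SE) higher with the homemade antibody, and to SPRED2, an inhibitor of RAS signalling, at −0.96 ± 0.21. CCDC5 (HAUS1, of the mitotic spindle) differed by 0.78 ± 0.17, DTX2 by −0.61 ± 0.14 and GSTCD by 0.60 ± 0.14. Both Upstate immunoprecipitations form a scan batch of their own, so antibody and batch cannot be told apart.

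The knockdown against IgG asks what the macroH2A1 antibody still brings down. EVC2 was higher in the knockdown by 1.2 ± 0.24 (SE), at 2.02 ± 0.66 (SD, n = 3) against 0.83 ± 0.24 (SD, n = 3), TXNL6 (NXNL1) by 1.06 ± 0.19 and the growth factor gene EGF by 0.96 ± 0.16. RARB was lower by a log2 difference of −0.85 ± 0.21, and the interferon-induced gene GBP1 and the glucuronosyltransferase gene UGT2A3 each by −0.59 (SE 0.14 and 0.15). The leading macroH2A1 target GIMAP5 averaged −0.01 ± 0.09 (SD, n = 3) in the knockdown and −0.31 ± 0.20 (SD, n = 3) in IgG. In all 1739 promoters were higher and 15 lower (limma, 5714 at an unadjusted p under 0.05, smallest adjusted p = 0.0323). No promoter passed with arrays scaled to the same spread (2141 at an unadjusted p under 0.05), without centring (3663), within the first batch (48), or when IgG replicate 2 was left out, whereas 6130 were higher without IgG replicate 1. None of the 6 named promoters kept its call in every fit that left out 1 immunoprecipitation.

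The average profile around transcription starts asks where within promoters the variants sit. After subtraction of IgG both variants lay higher upstream than at the start, but groups of these sizes are too small for any difference to pass the exact permutation test after adjustment. Relative to IgG, macroH2A1 stood at 0.33 ± 0.03 (SD, n = 4) in the bin 2500 bp upstream and at 0.02 ± 0.11 at the start, and macroH2A2 at 0.41 ± 0.10 (SD, n = 3) and −0.22 ± 0.02. The knockdown stood at 0.15 ± 0.05 (SD, n = 3) and 0.17 ± 0.12. These SDs leave out the spread of IgG itself, whose SD (n = 3) was 0.18 in the upstream bin and 0.03 at the start. The start minus the bins over 2 kb upstream was 0.45 ± 0.09 for macroH2A1, 0.14 ± 0.11 for macroH2A2, 0.77 ± 0.10 for the knockdown and 0.75 ± 0.21 for IgG. The difference from IgG was −0.29 for macroH2A1 (exact permutation p = 0.0857, two-sided, adjusted 0.15), −0.61 for macroH2A2 (exact p = 0.1, the smallest that 3 against 3 allow, adjusted 0.15) and 0.02 for the knockdown (exact p = 1). After GC correction of each array the differences were −0.10 (exact p = 0.0286, the smallest that 4 against 3 allow, adjusted 0.0857), −0.17 (0.1, adjusted 0.15) and 0.06 (0.3).

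**Figure D4:**
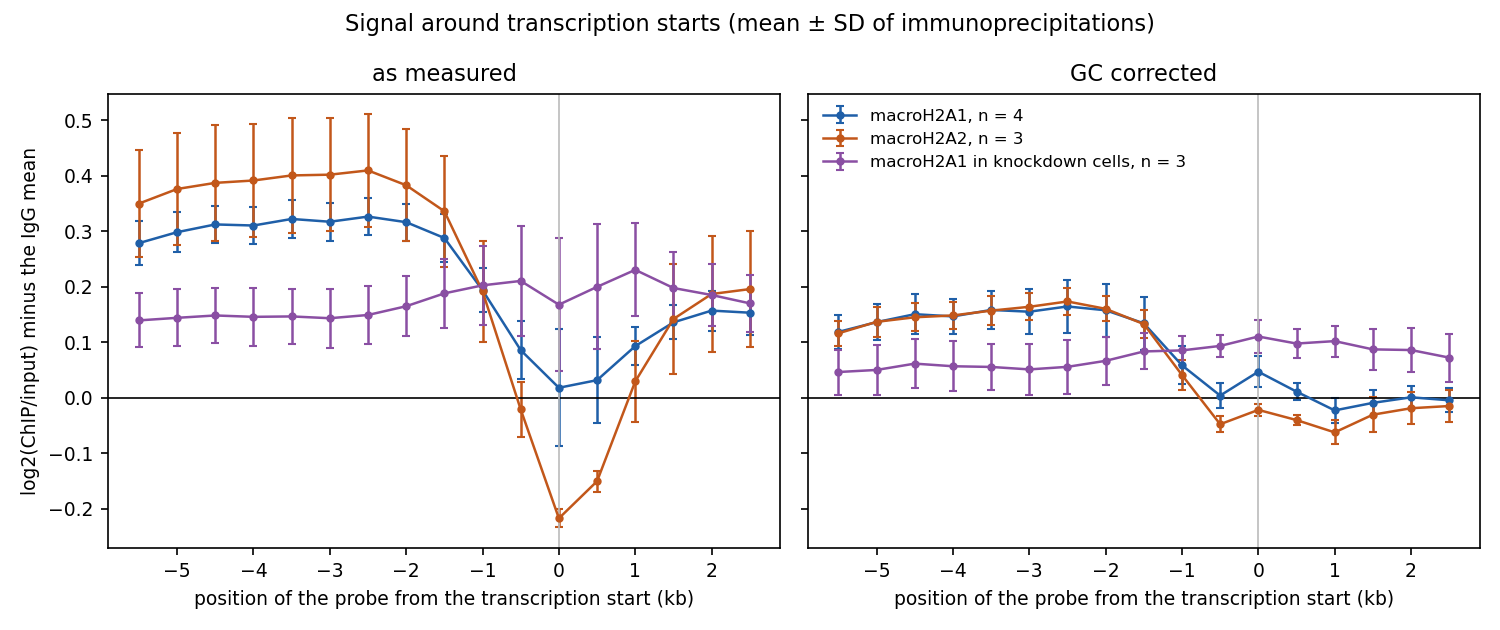
Mean log2 ratio minus the IgG mean (y axis) by distance from the transcription start in kb (x axis), in bins of 500 bp, as measured and after GC correction. Lines are group means, and bars are the SD within each group, without the spread of IgG. As measured, macroH2A2 falls from 0.41 in the bin 2500 bp upstream to −0.22 at the start, and macroH2A1 from 0.33 to 0.02.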

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

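The tests of GC content, scan batch and array spread for the HOX clusters, of GC content for chromosome 12 and of a wrong label for homemade replicate 2 were chosen only after the result was seen.

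Among the 4 macroH2A1 immunoprecipitations, 45 named promoters were tested for a sample far from the others, and 6 stood beyond the critical value, where chance gives about 1 in 20. The gap divided by the range was 0.8344 at HOXA3, 0.9492 at HOXA10, 0.8368 at HOXD13, 0.9347 at HOXD3 and 0.8934 at CLCN3, all set apart by homemade replicate 2, and 0.9551 at ZNF234, set apart by homemade replicate 1. Homemade replicate 2 stood at −0.03 at HOXA3 (others 0.59 to 0.71), 0.39 at HOXA10 (0.98 to 1.01), 0.30 at HOXD13 (0.72 to 0.80), 0.12 at HOXD3 (0.65 to 0.69) and −0.24 at CLCN3 (−0.72 to −0.67). Homemade replicate 1 stood at −0.46 at ZNF234 (others −0.66 to −0.65).

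Homemade replicate 2 was low at the HOX clusters, at a mean of 0.22 against 0.57 to 0.65 in the other macroH2A1 immunoprecipitations. The gap divided by the range was 0.802 as measured, under the critical value to begin with, so the values with arrays scaled to the same spread (0.32029) and after GC correction (0.50723) decide nothing on array spread or GC content. A wrong label stays open too: over the promoters higher in the other three than in IgG, its mean minus the highest knockdown mean was 0.00043116, and its HOX mean lay within the knockdown range of 0.16 to 0.30. Across promoters it correlated with the other macroH2A1 immunoprecipitations at 0.832 to 0.844, which correlated with each other at 0.949 to 0.986. It correlated with IgG at 0.785 to 0.854, highest with IgG replicate 1, and with the knockdown at 0.805 to 0.835. The IgG immunoprecipitations correlated with each other at 0.892 to 0.932 and the knockdown ones at 0.95 to 0.99. Homemade replicate 2 thus stood apart from each of these groups, so the correlations do not decide its label. At GIMAP5, though, it lay far above every knockdown value, and no biological explanation was tested.

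HOX promoters were higher with macroH2A1 than IgG by a mean of 0.56 (SE 0.0895). After GC correction the difference was 0.42051 (SE 0.0702) and with arrays scaled to the same spread 0.50973 (SE 0.0610), which argues against GC content or spread as the whole cause. Within the first scan batch, with both homemade and 1 IgG immunoprecipitation, it was 0.32821 (SE 0.189). That is too imprecise to tell whether scan batch adds to the difference. Occupancy by macroH2A1 stays among the open explanations.

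Promoters in the first 35 Mb of chromosome 12 were higher with macroH2A2 than IgG by a mean of 0.735 (SE 0.170), against 0.112 elsewhere. After GC correction 0.47422 (SE 0.111) remained, which argues against GC content as the whole cause. The residual from promoters of like GC content and input signal was 0.29041, reached by 3 of 548 windows of 5 Mb elsewhere (highest 0.353), so input brightness stays open. The input signal itself was higher there than at promoters of like GC content, by 0.73 ± 0.12 (SD, n = 3) on IgG and 0.85 ± 0.05 (SD, n = 3) on macroH2A2 arrays. The immunoprecipitated signal was −0.03 ± 0.16 on IgG, 0.08 ± 0.12 on knockdown (SD, n = 3 each) and 0.65 ± 0.06 (SD, n = 3) on macroH2A2 arrays. On macroH2A1 arrays it was 0.49 ± 0.17 with the homemade and 0.45 ± 0.04 with the Upstate antibody (SD, n = 2 each). With macroH2A1, 38.6% of these promoters were called higher than IgG, against 14.8% elsewhere, so the pattern was not limited to macroH2A2.

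Splits of the samples in other ways into groups of the same sizes, in fits of only those samples with the macroH2A1 antibodies as a single group, asked whether chance can be excluded. For macroH2A1 against IgG it cannot: the real split gave 1497 promoters and 2 of 35 splits gave as many, with 1573 when homemade replicate 2 joined the IgG samples. For macroH2A1 against macroH2A2 the real split gave 0 in limma (5642 at an unadjusted p under 0.05 with the antibodies as separate groups), so 35 of 35 splits give as many whatever the data and the count decides nothing, with 7052 as the highest other, when homemade replicate 2 joined macroH2A2 (0 with arrays scaled to the same spread, 124 after GC correction). The same holds for the knockdown against IgG (real 0, 4392 at an unadjusted p under 0.05, highest other 0, with 10 of 10 splits as large). For macroH2A2 against IgG (real 3437, highest other 0, with 1 of 10 splits as large) the splits are too few for a share under 0.05.

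Between the variants, under the camera test of the difference itself, developmental transcription factors stood at 0.09295 (−0.22 with arrays scaled to the same spread), olfactory receptors at −0.2792 (0.01 in the authors' scores), taste receptors at −0.2408 (0.17 with arrays scaled) and keratins at −0.154. With an estimated correlation the adjusted p was 0.995 for each.

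Probes outside the named promoters, 8634 in 455 regions, were higher at 123 regions with macroH2A1 than IgG (27.0% against 15.2% of named promoters) and at 159 with macroH2A2 than IgG (34.9% against 20.2%). The knockdown was higher than IgG at 7 of them (1.54% against 9.96% of named promoters). At an unadjusted p under 0.05 in limma, it differed from IgG at 128 of the 455 regions and 5714 of 17458 promoters. The called shares alone therefore do not show that regions and promoters differ.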

How the results depend on the processing

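GC correction, that correction with scaling, and scan batch as a random block were chosen only after the result was seen. Counts below are promoters higher and then lower in limma, with shared targets where they moved, and the cause of a change was not tested unless stated. Signal well above background was marked with a multiplier of 13 on IgG replicates 2 and 3 and 2.6 elsewhere, so that alternative treats those arrays unlike the rest. Scan batch as a block gives no antibody comparison, since both Upstate samples form a batch of their own. Under that block, macroH2A1 against IgG or macroH2A2 used the homemade antibody alone. Every difference under the block equals that within the first batch, so both alternatives share the same differences. Of 146 named results with a value, 146 kept their side of the threshold with each design on its own and with eBayes trend and robust. Each promoter lies on a single design, so neither alternative changes a difference and direction could not turn there. Direction and side of the threshold were kept by 137 with GC correction, 135 with loess, 105 with arrays scaled and 43 with normexp. Within the first batch, which holds 1 IgG and 1 knockdown immunoprecipitation, all 141 named results with a value kept their direction (GIMAP5 1.85 in macroH2A1 against IgG). That says little on scan batch, because the same immunoprecipitations entered the naming. Leading promoters were picked for no overlap between the groups' values, which fixes their direction in any subset. Leave-outs kept 1713 of 1898.

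With normexp, macroH2A1 against IgG gave 0 and 0 (892 at an unadjusted p under 0.05), macroH2A2 against IgG 0 and 0 (2952), wild type against knockdown 2698 higher, the knockdown against IgG 0 and 0 (2904), and shared targets 0. Developmental transcription factors stood at −0.00902 in macroH2A2 against IgG and −0.11093 in wild type against knockdown, and HOXA at −0.22635 in the latter. With loess, macroH2A1 against IgG gave 1093 lower, wild type against knockdown 873 lower, macroH2A1 against macroH2A2 2 and 3, the knockdown against IgG 771 and 114, shared targets 1251, and olfactory receptors in macroH2A1 against IgG −0.008512.

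Without centring, macroH2A1 against IgG gave 4380 and 12, macroH2A2 against IgG 88 lower, wild type against knockdown 305 and 37, the knockdown against IgG 0 and 0 (3663 at an unadjusted p under 0.05), and shared targets 3091. With arrays scaled to the same spread, macroH2A1 against IgG gave 1487 higher, macroH2A2 against IgG 2330 lower, wild type against knockdown 288 and 695, macroH2A1 against macroH2A2 484 and 225, the knockdown against IgG 0 and 0 (2141), shared targets 1361 and 78 list calls. Scaling turned TAS2R50 (0.20444), developmental transcription factors (−0.2214) and taste receptors (0.16536) in macroH2A1 against macroH2A2, and olfactory receptors in wild type against knockdown (−0.10238).

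With probes well above background only, macroH2A1 against IgG gave 154 and 18, macroH2A2 against IgG 921 and 268, wild type against knockdown 110 and 87, macroH2A1 against macroH2A2 2 higher, the antibodies 1 lower, the knockdown against IgG 1 and 0, and shared targets 137. Histone genes stood at −0.051893 and cytokines at −0.005855 in wild type against knockdown. With the median of the probes, macroH2A1 against IgG gave 653 and 172, macroH2A2 against IgG 2144 and 483, wild type against knockdown 1426 higher, the knockdown against IgG 0 and 0 (4558 at an unadjusted p under 0.05), and shared targets 602. With at least 10 probes the knockdown against IgG gave 5 lower, with fewer promoters tested.

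In the authors' scores, macroH2A1 against IgG gave 13 and 9, macroH2A2 against IgG 1638 and 1391, wild type against knockdown 37 and 54, macroH2A1 against macroH2A2 51 and 195, the antibodies 1 and 2, the knockdown against IgG 0 and 0 (938 at an unadjusted p under 0.05), and shared targets 13. These were mostly other promoters than in the main fit. Of the main increases against IgG, 12 with macroH2A1 and 573 with macroH2A2 were kept, while 659 and 1226 turned sign. Kept decreases numbered 0 and 79. Across promoters the differences correlated with those of the main fit at r = 0.377 and 0.125. Olfactory receptors stood at −0.025283 in macroH2A1 against IgG, −0.034624 in macroH2A2 against IgG, −0.018076 in wild type against knockdown and 0.009342 in macroH2A1 against macroH2A2. Histone genes stood at −0.015389 in wild type against knockdown, and TAS2R50 at 0.084506, developmental transcription factors at −0.015219 and taste receptors at 0.049646 in macroH2A1 against macroH2A2.

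With a block by replicate number, macroH2A1 against IgG gave 1020 and 11, macroH2A2 against IgG 241 lower, wild type against knockdown 206 and 174, the knockdown against IgG 0 and 0 (2990 at an unadjusted p under 0.05), and shared targets 921. The numbers were those in the labels, so knockdown replicate 3 shared number 1 with knockdown replicate 1. They are not shown to pair samples across groups: 18 pairs of the same number correlated at −0.385 to 0.564 (median −0.0959), highest between homemade macroH2A1 and macroH2A2, so calls lost with this block do not show weaker effects. With scan batch as a block, macroH2A1 against IgG gave 0 and 0 (1580), macroH2A2 against IgG 267 and 104, wild type against knockdown 5 and 0, the knockdown against IgG 0 and 0 (164), and shared targets 0. With scan batch as a random block the counts were 433 and 3, 1433 and 166, 64 and 20, and 0 and 0 (1354), with 393 shared targets. Within the first batch these 4 comparisons gave 0 and 0 (721, 2366, 1039 and 48) and shared targets 0, with single IgG and knockdown samples assumed to vary like the other groups.

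With only the groups compared and the antibodies as separate groups, macroH2A1 against IgG gave 1419 and 16, wild type against knockdown 438 and 529, the knockdown against IgG 0 and 0 (4392 at an unadjusted p under 0.05), and shared targets 1242. With eBayes trend and robust, macroH2A1 against macroH2A2 gave 3 higher and the knockdown against IgG 3713 and 38. The homemade antibody alone against IgG gave 759 and 13, and both antibodies against the knockdown 1070 higher. Camera with an estimated correlation called 0 lists, and fry 26.

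With GC correction, macroH2A1 against IgG gave 1531 lower, macroH2A2 against IgG 2551 lower, wild type against knockdown 1341 higher, the knockdown against IgG 145 higher, and the start profile of macroH2A1 differed by −0.10308. With GC correction and scaling, macroH2A1 against IgG gave 916 lower, macroH2A2 against IgG 3363 lower, wild type against knockdown 1146 and 1054, macroH2A1 against macroH2A2 359 and 622, the antibodies 1 higher, the knockdown against IgG 0 and 0 (1087 at an unadjusted p under 0.05), 82 list calls, and the start profile of macroH2A1 −0.084063. In macroH2A1 against macroH2A2 it put developmental transcription factors at −0.15147 and taste receptors at 0.059886.

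Leaving out each immunoprecipitation gave these lowest and highest counts, higher and then lower: macroH2A1 against IgG 886 (without IgG replicate 3) to 5363 (without IgG replicate 1) and 12 to 292, macroH2A2 against IgG 1963 (without macroH2A2 replicate 2) to 5729 (without IgG replicate 1) and 170 to 1236. Wild type against knockdown ran from 31 (without knockdown replicate 2) to 1172 and 5 to 3252, macroH2A1 against macroH2A2 from 0 to 2105 and 0 to 512 (both highest without homemade replicate 2), the antibodies from 0 to 21 and 0 to 2, and the knockdown against IgG from 0 to 6130 and 0 to 76. Shared targets ran from 740 to 4215, list calls from 34 to 64, and the start profile from −0.4162 to −0.22284 for macroH2A1 and −0.73079 to −0.53743 for macroH2A2. Where this left 1 homemade sample, it was assumed to vary like the other groups. The list of developmental transcription factors in macroH2A1 wild type versus knockdown ran from −0.034494 without homemade replicate 1 to 0.25527 without homemade replicate 2, and replication-dependent histone genes in macroH2A1 wild type versus knockdown from −0.060633 without homemade replicate 2 to 0.47221 without homemade replicate 1.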
